A study of Mus musculus with 6 samples.

How the data were processed

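Back epidermis of mice was profiled by RNA-seq in 3 samples of floxed Spry1 controls and 3 samples with floxed Spry1 and K14-Cre-ERT2. Per the labels' protocols, all mice received tamoxifen by gavage at 0.1 mg per g body weight, 4 times a week over 4 weeks, from a 20 mg per ml solution, and libraries were made from 0.4 ug of total RNA extracted with Trizol. Groups and replicate numbers were taken from the sample titles.

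The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to a common sequencing depth) for 54532 genes, with 1 column per sample. HISAT2 2.0.5 and featureCounts 1.5.0-p3 are named, with the mouse build GRCm38, per the submitters' processing notes. The annotation release, the strandedness of the libraries, filters and the FPKM formula are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. FPKM depends on the gene length and the total used for scaling, and a few abundant genes can shift all others. The 10 most abundant genes held 12.6% to 16.0% of the FPKM sum in the controls and 18.6% to 22.2% in the knockouts.

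Gene positions and types were taken from GENCODE M21 (GRCm38) by gene ID, which matched 54495 IDs. Of the gene names, 27 had been turned into dates and were replaced by ID. FPKM multiplied by the exon length came out as whole multiples of one step per sample for 97.0% to 97.3% of values (tolerance 0.1 reads, where chance gives 20%). The recovered reads summed to 18383323 to 21024715 per sample. The totals the authors scaled by, read from the steps, were 98.8% to 102.9% of these sums in the controls and 88.1% to 95.6% in the knockouts.

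The test was limma 3.58.1 (R 4.3.3) with a trend on log2(FPKM + 1), two-sided, with genotype as the only term, over genes with a mean of at least 1 FPKM. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale and understates the change of low genes. Fixed gene lists, 38 with 519 distinct genes of which 518 matched the table, were tested with camera at an inter-gene correlation of 0.01 where at least 3 genes passed the filter, with a variance trend as in the gene test. The plan did not state that trend, and an earlier look at the lists had been made without it. Camera with an estimated correlation and fry were run beside it. The gene lists, the design and the alternatives were fixed before the data were examined, except where stated.

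Named genes followed a rule: the Sprouty and Spred family; the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap, leaving out symbols of unnamed loci; of each list up to 4 members past the threshold with the lowest p, or at most 2 of a list with none; and Kitl, Kit, Trp53 and Cdkn1a. Some genes that the rule selects are not reported here. Others were chosen after their values were seen: Cry1, Arntl, Clock, Per1, Dct, Rab27a, Adgre1, Ache, Trac, Cd4, Cd8a, Thy1, Cd2, Lck, Tcrg-C1, Skint9, Il19, Il24, Hoxa5, Hoxa7, Hoxb9, Ddx3y and the hair keratins. Krt14, Krt5 and Mitf were chosen then as well, and were not followed gene by gene under the alternatives.

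The gene test was tested on reads simulated from the control means, with a set dispersion of 0.02. A small share of genes was changed by known folds in the simulated knockouts. At a true 2-fold change 63 of 67 genes were recovered, at 1.5-fold 22 of 67, and 16 of 12373 unchanged genes were called. Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, array weights, a replicate block, leaving out each sample, protein-coding genes, and a fold of at least 2. Added after seeing the data were limma-voom on recovered reads, TPM scaling, scaling to recovered reads, leaving out Control replicate 3 and Spry1_KO replicate 2 together, and camera without a variance trend. Chi-square per gene between replicates ran from 14.1 to 83.9, so no pair agreed within sampling noise. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.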

Results

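The series compared back epidermis of mice in which Spry1 had been deleted from keratinocytes with back epidermis of mice that kept the gene. Spry1 encodes Sprouty1, a feedback inhibitor of receptor tyrosine kinase signalling to ERK. The knockout animals carried floxed Spry1 and a tamoxifen-inducible Cre recombinase under the keratin 14 promoter, which is active in basal keratinocytes. Controls carried floxed Spry1 without Cre, and both genotypes received tamoxifen. No sample carried Cre without floxed Spry1, so effects of Cre itself and of Spry1 loss cannot be told apart. There were 3 control and 3 knockout RNA-seq samples. Reads recovered from the FPKM values ranged from 18383323 to 21024715 per sample. The labels do not say that the samples are separate animals, so p-values measure only the spread between these samples, which may in part be technical.

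Spry1 was low in every knockout sample. It read 25.8, 28.2 and 34.4 FPKM in the controls and 1.06, 1.49 and 1.28 FPKM in the knockouts. The gene lies on chromosome 3 from 37639947 to 37644598 in GRCm38. Its log2 fold change was -3.74 ± 0.13 (SE), with a limma adjusted p of 7.21e-06. Of the other members of the Sprouty and Spred family, Spry2 fell from 18.2 ± 1.78 to 9.15 ± 1.85 FPKM (SD, n = 3 each), with a limma adjusted p of 0.00175. Spred2 fell with a limma adjusted p of 0.0426 and Spred1 rose with 0.00229. The call for Spred2 was lost without Spry1_KO replicate 2 (limma adjusted p of 0.117), Spry1_KO replicate 1 (0.0697), Spry1_KO replicate 3 (0.106) or Control replicate 2 (0.0721) and without Control replicate 3 and Spry1_KO replicate 2 together (limma adjusted p of 0.0995), and that for Spred1 under TPM scaling (0.127). Of the 7 family members, 3 lay below the filter: Spry4 read 0.654 and 0.358 FPKM in controls and knockouts, Spred3 0.127 and 0.357, and Spry3 0.0123 and 0.157. Adjusted over the list alone, 1 member rose and 3 fell, and the list did not pass camera (adjusted p of 0.212).

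**Figure D1:**
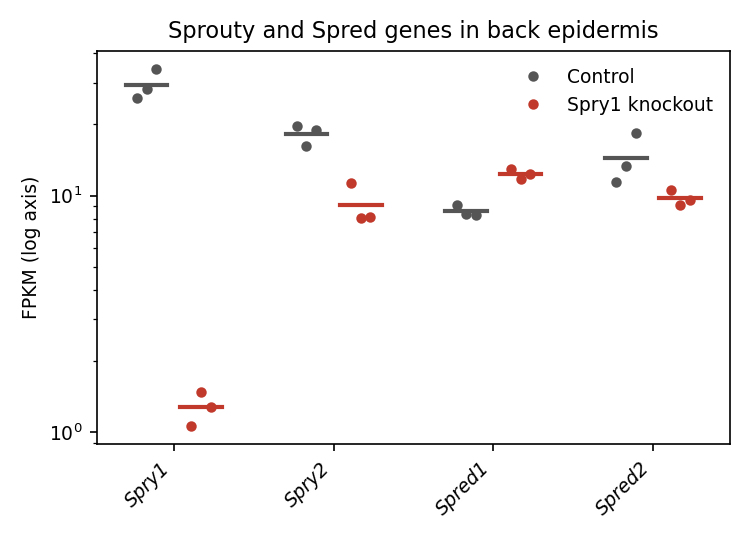
FPKM per sample on a log axis for Spry1, Spry2, Spred1 and Spred2; points are samples, bars are group means of 3. Spry1 lies between 25.8 and 34.4 FPKM in the controls and between 1.06 and 1.49 FPKM in the knockouts.

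The difference between the genotypes reached about as many genes as it left. Of 12629 genes tested, 3736 were higher and 3079 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05). These were 6815 in all, or 54% of those tested. Counts of list members past the threshold are to be read against that share. A change of at least 2-fold on the log2(FPKM + 1) scale was seen for 1024 of the risen and 1010 of the fallen genes. In 64.2% of tested genes the groups did not overlap, where chance gives 10%. The first principal component held 82.7% of the variance and parted the genotypes. Correlations ran from 0.962 to 0.986 within a genotype and from 0.838 to 0.863 between them. The split into higher and lower calls depended on the scaling. TPM scaling moved the median of all genes by -0.23 and gave 2057 higher and 4455 lower genes, and scaling to recovered reads gave 2900 and 3743. Control replicate 3 stood apart on the second component (8.5% of the variance). Spry1_KO replicate 2 read 19.25 FPKM for the Y-linked gene Eif2s3y, against 0.203 and 0.044 FPKM in the other knockout samples. It was therefore not a second sample of the same tissue, though tissue shared in part is not excluded. Without Control replicate 3 and Spry1_KO replicate 2 together, 6707 genes passed.

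**Figure D2:**
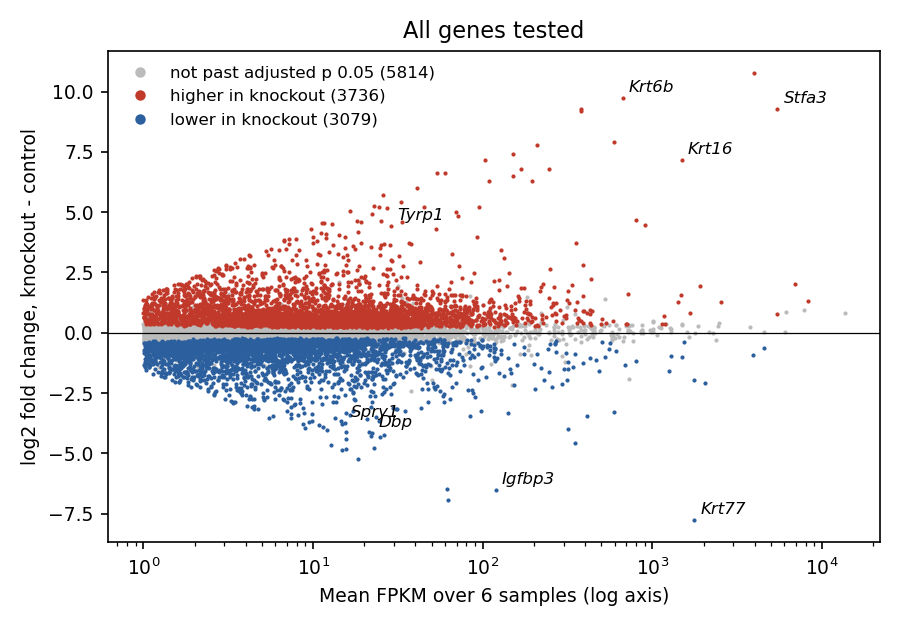
Mean FPKM over 6 samples (log axis) against log2 fold change, knockout minus control, for the 12629 genes tested; colour marks the 3736 higher, 3079 lower and 5814 remaining genes. Krt6b lies at 9.74 and Krt77 at -7.77.

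Genes of injured and hyperproliferative epidermis rose most. Krt6b, a keratin of wounded skin, went from 0.551 ± 0.395 to 1333 ± 414 FPKM (SD, n = 3 each), a log2 fold change of 9.74 ± 0.26 (SE) with a limma adjusted p of 3.71e-06. Krt16, its type I partner keratin, went from 21.7 to 2955 FPKM. Sprr1b, a cross-linked protein of the cornified envelope, went from 0.316 to 758 FPKM. The cystatin genes Stfa1, Stfa2 and Stfa3 had log2 fold changes of 7.93, 9.27 and 9.29, and Serpinb3a had 7.16. The alarmin gene S100a8 went from 2.17 to 301 FPKM. Sprr2a1, Sprr2a2 and Sprr2d rose by 6.78, 7.39 and 6.62 on the log2 scale, but the annotated spans of Sprr2a1 and Sprr2a2 overlap and the Sprr2 and Stfa families hold close copies, so the share of each copy is uncertain. Without Control replicate 2 Sprr2a1 and Sprr2a2 rose by 7.43 and 7.99. Chil4, a chitinase-like gene, was listed at 0 in the controls and averaged 417 ± 428 FPKM in the knockouts, a spread as large as its mean, and it did not pass in limma-voom on recovered reads (adjusted p of 0.0933). Its log2 fold change was 7.80, 9.09 without Spry1_KO replicate 2 and 6.80 without Spry1_KO replicate 3. On the list of stress keratins and alarmins all 23 tested members rose, also when adjusted over the list alone (median log2 fold change 4.85, camera adjusted p of 8.38e-12, adjusted p = 0.538 with an estimated correlation).

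The 12 largest falls included the keratin gene Krt77 and the gamma-delta receptor segment Tcrg-V5. Krt77, a suprabasal keratin, fell from 3500 ± 391 to 16.6 ± 9.88 FPKM (SD, n = 3 each), a log2 fold change of -7.77 ± 0.35 (SE) with a limma adjusted p of 1.72e-05. Igfbp3, an insulin-like growth factor binding protein, fell from 237 to 1.78 FPKM, and Ifitm6 from 122 to 0.292 FPKM. Sema3d and Gpha2 had log2 fold changes of -4.83 and -4.41. Lce1m fell from 685 ± 554 to 16.3 ± 3.78 FPKM (SD, n = 3 each), a log2 fold change of -4.56 that was -5.85 without Control replicate 3 and -3.82 without Control replicate 1. Skint5, of a keratinocyte family linked to the selection of epidermal gamma-delta T cells, fell from 45.3 to 0.675 FPKM, and Tcrg-V5 from 42.8 to 1.26 FPKM. Among these falls were Mrgprb genes that lie near each other on chromosome 7. Mrgprb3 had a log2 fold change of -4.87, Mrgprb11-ps -6.94 and Mrgprb9-ps -5.22. Mrgprb9-ps and the nearby Mrgprb2, of the mast cell list, were listed at 0 in the knockouts. The rule picked these genes, and the Mrgprb family as a whole was not tested. Mir8116 fell by 4.31 on the log2 scale, or 3.71 without Spry1_KO replicate 3, but it lies on the same strand within Ache, which fell by 3.26, so its reads cannot be told from those of Ache.

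Genes of pigment cells rose nearly as a group. Of 15 tested members of the melanocyte and pigmentation list, 13 rose and 1 fell, with the same counts adjusted over the list alone (median log2 fold change 1.81). Mlana went from 0.641 ± 0.489 to 37.6 ± 3.27 FPKM, Tyrp1 from 1.76 ± 0.840 to 56.2 ± 2.21 and Pmel from 4.62 ± 0.789 to 70.5 ± 0.562 (SD, n = 3 each). Gpnmb had a log2 fold change of 2.50. The member that fell was Rab27a, which carries melanosomes to the cell periphery (-1.42). Mitf, the remaining member, read 2.80 FPKM in controls and 2.42 in knockouts and did not pass (limma adjusted p of 0.343). Kit, the receptor of stem cell factor, went from 0.489 to 3.27 FPKM, and Kitl, which encodes stem cell factor, from 1.25 to 3.98 FPKM, with limma adjusted p values of 0.000171 and 0.000569. The list passed camera (adjusted p of 4.98e-06, and adjusted p = 0.459 with an estimated correlation). Among 6 tested keratinocyte factors acting on melanocytes, 3 rose and 3 fell, also adjusted over the list alone. Kitl was among those that rose, while Bmp4 fell by 4.04 on the log2 scale and Cxcl12 by 1.07.

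The p53 list moved both ways. Trp53 rose from 17.6 to 25.6 FPKM (log2 fold change 0.51 ± 0.11, SE; limma adjusted p of 0.00674), a call lost under TPM scaling (0.218). Cdkn1a, a p53 target that arrests the cell cycle, read 120 and 105 FPKM and did not pass (limma adjusted p of 0.255). It passed under TPM scaling alone (0.0453, lower). Of 28 tested p53 targets, 11 rose and 8 fell, or 12 and 9 adjusted over the list alone (camera adjusted p of 0.861). Psrc1 and Pmaip1 rose by 1.99 and 1.72 on the log2 scale, and Fas and Trp53inp1 fell by 1.16 and 1.49.

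Among ERK transcriptional targets, 8 of 15 tested rose and 2 fell, with the same counts adjusted over the list alone. Etv4, Phlda1 and Etv5 had log2 fold changes of 2.83, 2.33 and 1.37. The members that fell were Spry2 and Spred2, while Spred1, of the same family, rose (0.48). The list stood at the threshold (camera adjusted p of 0.0481, and adjusted p = 0.743 with an estimated correlation). Without a variance trend in camera, a choice the plan left open, its adjusted p was 0.0501. It did not pass without Control replicate 1 (0.067) or 2 (0.0575), without Spry1_KO replicate 1 (0.06) or 2 (0.0614), with a pseudocount of 0.1 (0.0517) or in limma-voom on recovered reads (0.0566). Without Control replicate 2 or any 1 of the knockout samples only 1 member fell. Of 11 tested EGFR ligands and receptors, 3 rose and 3 fell, also adjusted over the list alone. Tgfa rose by 1.06, and Lrig1, Erbb2 and Btc fell by 0.91, 0.51 and 2.02. Of 7 FGF ligands and receptors, 2 rose and 2 fell, also adjusted over the list alone. Fgfr1 and Fgfbp1 rose by 0.98 and 1.16, and Fgfr2 and Fgfr3 fell by 1.84 and 0.77. Neither list passed camera (adjusted p of 0.704 and 0.861). Btc no longer passed without any 1 sample other than Control replicate 3 (limma adjusted p of 0.064 to 0.0859), and the EGFR list had 1 risen and 2 fallen members without any 1 of these. Nor did Btc pass in limma-voom on recovered reads (0.0768), and without Control replicate 3 it fell by 2.81. The median of the EGFR list was -0.16 and its mean 0.09.

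Keratinocyte differentiation genes moved both ways, where 54% of all tested genes passed. In the cornified envelope list 14 of 28 tested rose and 2 fell, or 15 and 2 adjusted over the list alone (camera adjusted p of 0.00729, and adjusted p = 0.743 with an estimated correlation). Casp14, a protease of terminal differentiation, rose by 2.48 and Lce1g by 3.73, and Lce3a and Lce3b were listed at 0 in the controls. Without Control replicate 3 this list no longer passed (adjusted p of 0.115), with 17 members up and 7 down, nor without that sample and Spry1_KO replicate 2 together (0.13), and it did not pass fry (0.121). Of 14 suprabasal genes, 4 rose and 6 fell, also adjusted over the list alone. Krt1 rose from 782 to 3009 FPKM, while Dsg1a, Sbsn and Krt2 fell by 1.94, 1.44 and 1.85. Of 15 basal genes, 3 rose and 7 fell, also adjusted over the list alone. Krt15, Col17a1 and Dst fell by 2.10, 1.49 and 1.48, and Cdh3 rose by 1.21. The other risen members, named after their values were seen, were the abundant keratin genes Krt14 and Krt5. Krt14 went from 2706 to 11060 FPKM and Krt5 from 3962 to 6878 FPKM (limma adjusted p of 0.000493 and 0.00878). The suprabasal and basal lists did not pass camera (adjusted p of 0.442 and 0.225).

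Cell cycle genes rose in 19 of 22 tested, or 20 adjusted over the list alone, and none fell (median 1.83, camera adjusted p of 3.74e-07, and adjusted p = 0.743 with an estimated correlation). Plk1, Cdc20, Ccnb2 and Ccnb1, which act in mitosis, had log2 fold changes of 2.52, 2.44, 2.33 and 2.01. Antioxidant genes rose in 7 of 10, also adjusted over the list alone (camera adjusted p of 0.00806, and adjusted p = 0.743 with an estimated correlation), and 1 fell without Control replicate 3. Gsta4 went from 0.914 to 49.5 FPKM, and Nqo1, Srxn1 and Gclm had log2 fold changes of 1.83, 1.81 and 1.24. Cholesterol synthesis genes rose in 9 of 16, also adjusted over the list alone (camera adjusted p of 0.0325, and adjusted p = 0.743 with an estimated correlation). Idi1, Sqle and Lss had log2 fold changes of 1.58, 0.90 and 0.56. That list no longer passed without Control replicate 3 (adjusted p of 0.091), without Spry1_KO replicate 2 (0.0594), without both (0.147) or with array weights (0.0778). Barrier lipid genes rose in 7 and fell in 4 of 16, or 9 and 5 adjusted over the list alone (camera adjusted p of 0.704, median 0.35 and mean -0.01). Acer1 and Elovl1 fell by 2.10 and 1.07, and Alox12b and Sptlc2 rose by 0.69 and 0.55. Without Spry1_KO replicate 2 the barrier lipid counts were 4 up and 3 down, and without Spry1_KO replicate 3 they were 4 and 4.

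Circadian clock genes fell in 10 of 14 tested and rose in 2, or 10 and 3 adjusted over the list alone (median -1.80, camera adjusted p of 0.00102, and adjusted p = 0.509 with an estimated correlation). Dbp, a clock output factor, fell from 43.1 ± 3.87 to 1.47 ± 0.214 FPKM (SD, n = 3 each). Hlf, Tef and Nr1d2 fell by 2.87, 2.46 and 2.09. The members that rose, named after their values were seen, were Cry1 (0.74) and Arntl (0.49), and neither passed under TPM scaling (limma adjusted p of 0.12 and 0.189) or without Control replicate 1 (0.0535 and 0.101), Spry1_KO replicate 1 (0.0633 and 0.0869) or Spry1_KO replicate 3 (0.0719 and 0.104). Arntl did not pass without Control replicate 3 (0.0681) or scaled to recovered reads (0.0702) either.

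**Figure D3:**
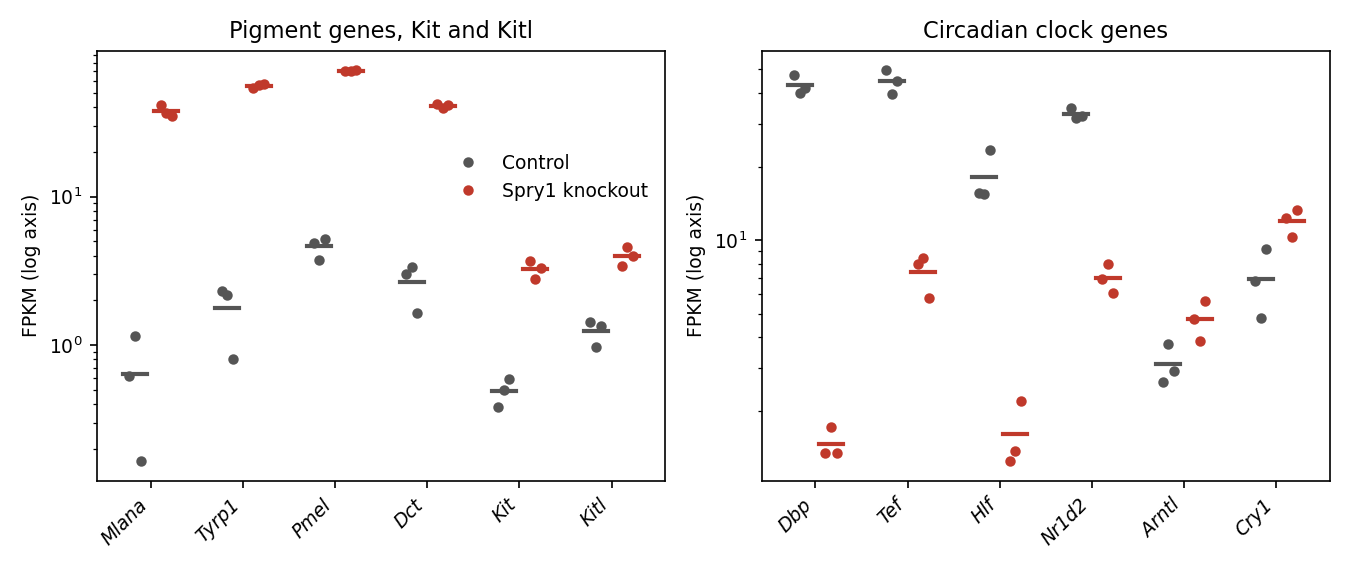
FPKM per sample on log axes for pigment genes with Kit and Kitl (left) and for clock genes (right); points are samples and bars are group means of 3. Tyrp1 averages 1.76 FPKM in controls and 56.2 FPKM in knockouts, and Dbp 43.1 and 1.47 FPKM.

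Immune genes moved in opposite directions. Of 10 T cell genes, 6 fell, also adjusted over the list alone (median -1.37, camera adjusted p of 0.00729, and adjusted p = 0.743 with an estimated correlation). Trdv4 and Trdc, of the gamma-delta receptor, fell by 3.13 and 2.73, and Cd3g and Cd3e by 2.04 and 1.68. Of 9 Langerhans cell genes, 7 fell, or 7 down and 1 up adjusted over the list alone (median -1.48, camera adjusted p of 0.00806, and adjusted p = 0.743 with an estimated correlation). In limma-voom on recovered reads, which held 4 of these genes, the list did not pass (0.315). Cd207, which encodes langerin, fell from 47.5 to 9.06 FPKM, and Csf1r, Cd74 and H2-Eb1 fell by 1.16, 1.61 and 1.63. Of 9 macrophage and neutrophil genes, 7 rose and Adgre1, a macrophage surface receptor, fell, with the same counts adjusted over the list alone (median 2.09, camera adjusted p of 0.00844, and adjusted p = 0.743 with an estimated correlation). That list did not pass in limma-voom on recovered reads (0.0563). The complement genes C1qb and C1qc had log2 fold changes of 3.22 and 2.70, and Cd14 and Cxcr2 2.49 and 2.03. Interferon response genes rose in 10 of 14 and fell in 1, also adjusted over the list alone (camera adjusted p of 0.00806, and adjusted p = 0.743 with an estimated correlation). Ifit1, Isg15, Ifit3 and Ifi27l2a had log2 fold changes of 2.16, 2.06, 2.04 and 1.48. Of 15 cytokine genes, 8 rose and 2 fell, also adjusted over the list alone, and the list did not pass camera (adjusted p of 0.0933). Tslp, Cxcl1 and Il1b rose by 3.59, 2.82 and 1.66, and Ccl27a fell by 2.55. The cytokine list passed camera without Control replicate 2 (adjusted p of 0.032), under TPM scaling (0.00899), scaled to recovered reads (0.0335) and with no filter (0.00151). Without Control replicate 2, Spry1_KO replicate 2 or Spry1_KO replicate 3 only 1 cytokine gene fell.

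**Figure D4:**
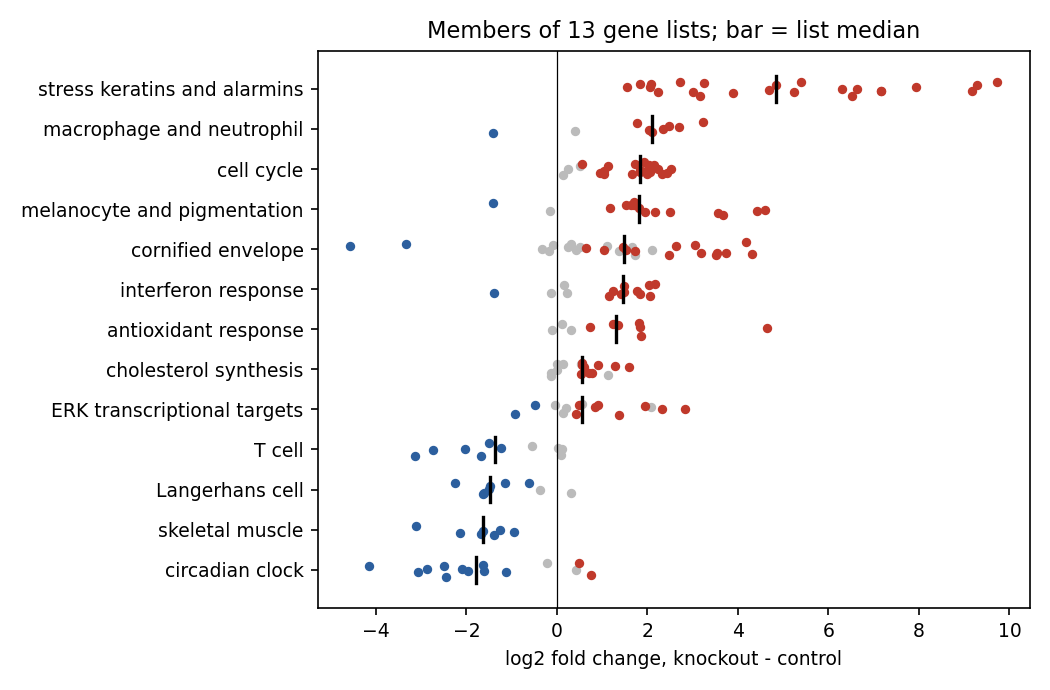
log2 fold change, knockout minus control, of each tested member of the 13 lists past camera's threshold; red members rose, blue fell, grey did not pass, and the black bar is the list median. The medians run from -1.80 for the circadian clock to 4.85 for stress keratins and alarmins.

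Markers of other tissue differed too. All 7 tested skeletal muscle genes were lower in the knockouts, also adjusted over the list alone (camera adjusted p of 0.00806, and adjusted p = 0.743 with an estimated correlation). Acta1 read 16.7 ± 12.5 and 0.786 ± 0.426 FPKM (SD, n = 3 each), and Atp2a1, Ckm and Pvalb fell by 1.68, 1.40 and 2.15. Without Control replicate 1 only 3 of 5 tested muscle genes passed, and without Control replicate 2 only 4 of 6. Of 8 fibroblast genes, 2 rose and 4 fell, or 2 and 6 adjusted over the list alone (camera adjusted p of 0.263). Postn and Sparc rose by 3.09 and 0.52, and Dpt and Col6a1 fell by 1.37 and 0.66. Sparc no longer passed without Spry1_KO replicate 1 (limma adjusted p of 0.0538), under TPM scaling (0.284) or scaled to recovered reads (0.0646), and 2 fibroblast genes rose and 2 fell without Control replicate 3, and 1 rose and 2 fell without Spry1_KO replicate 1. Of 5 red blood cell genes, Hba-a1 alone fell (-1.77) and none passed adjusted over the list alone (camera adjusted p of 0.224). Hba-a1 no longer passed without Control replicate 1 (limma adjusted p of 0.0779) or 2 (0.0787) or without Spry1_KO replicate 1 (0.0693), where none of these genes passed. There were 4 without Control replicate 3 and 2 without Spry1_KO replicate 3. Of 3 adipocyte genes, Fabp4 and Lpl rose (0.76 and 0.91), also adjusted over the list alone (camera adjusted p of 0.585), and the call for Fabp4 was lost without Control replicate 2 (limma adjusted p of 0.0931) or 3 (0.0765) and without Spry1_KO replicate 2 (0.102) or 3 (0.0984), under TPM scaling (0.0541), with array weights (0.0539) and without Control replicate 3 and Spry1_KO replicate 2 together (0.168). Lpl no longer passed without these together (0.0607). Lists with fewer than 3 tested genes had no camera test. Acta2, the only 1 of 8 smooth muscle genes tested, rose by 1.11. Mrgprb2, the only 1 of 6 mast cell genes tested, fell by 2.91. Ighm, the only 1 of 5 B cell genes tested, fell by 0.97. Mbp, from 2 tested of 7 Schwann cell genes, fell by 0.63. The other members lay below the filter, so these genes do not show a change of the cell type. No endothelial gene passed the filter. Mbp no longer passed without Control replicate 3 (limma adjusted p of 0.053) or without Spry1_KO replicate 1 (0.0824) or 2 (0.0765) or without Control replicate 3 and Spry1_KO replicate 2 together (0.117).

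The remaining lists did not pass camera. Of 11 hair follicle stem cell genes, 4 rose and 2 fell, also adjusted over the list alone (adjusted p of 0.305). Gli2, Fzd2 and Nfatc1 rose by 1.37, 1.12 and 0.81, and Lgr6 fell by 1.08. The counts were 6 up and 1 down without Control replicate 1, 4 and 1 without Spry1_KO replicate 1, and 3 and 1 without Control replicate 2, Spry1_KO replicate 2 or Spry1_KO replicate 3. Of 7 hair shaft and inner root sheath genes, 2 rose and 3 fell, also adjusted over the list alone (0.255). Krt32, Gata3 and Msx2 fell by 2.30, 2.23 and 0.62, and Hoxc13 rose by 0.89. Msx2 passed without Spry1_KO replicate 2, but not without any 1 of the other samples (limma adjusted p of 0.0525 to 0.0826). Only 1 gene of this list rose without Control replicate 1, Control replicate 2, Spry1_KO replicate 1 or Spry1_KO replicate 2. Of 14 sebaceous gland genes, Elovl3, Far2, Awat1 and Mgst1 rose (2.75, 1.73, 1.55 and 1.36), and none passed adjusted over the list alone (0.192). Without Spry1_KO replicate 1, 2 and 3 in turn, 2, 1 and 0 sebaceous genes passed, and without Control replicate 3 there were 4 up and 2 down. The list passed camera without Control replicate 2, with 8 risen members (0.00997), under TPM scaling (0.0172) and with no filter (0.027). Without Control replicate 3 Elovl3 and Awat1 rose by 1.93 and 0.94, and Awat1 did not pass with a pseudocount of 0.1 (limma adjusted p of 0.0565). Of 4 Wnt targets, 1 rose and 2 fell, or 1 and 3 adjusted over the list alone (0.411). Axin2 and Rnf43 fell by 1.20 and 0.74, and Tcf7 rose by 0.67. Rnf43 no longer passed without Spry1_KO replicate 3 (limma adjusted p of 0.0529) or without Control replicate 3 and Spry1_KO replicate 2 together (0.0716). Of 9 Notch genes, Hey1 rose (0.64), and Dll1 and Jag2 fell (-1.32 and -1.03), also adjusted over the list alone (0.403). Without any 1 of the knockout samples Hey1 lay below the filter, so that no Notch gene rose. Of 12 immediate early and heat shock genes, 1 rose and 3 fell, also adjusted over the list alone (0.0933). Fosb, Jun and Hspa1a fell by 2.15, 1.32 and 0.54, and Hspa1b, a near-identical copy of Hspa1a, rose by 0.40, a call lost under TPM scaling (limma adjusted p of 0.406) and scaled to recovered reads (0.0539). Fosb no longer passed without Spry1_KO replicate 1 (limma adjusted p of 0.054) or 3 (0.0903), nor Jun without any 1 control (0.0521 to 0.083) or Spry1_KO replicate 2 (0.059) or without Control replicate 3 and Spry1_KO replicate 2 together (0.107). Fosb fell by 1.43 without Control replicate 3. This list passed camera without Control replicate 1, with 5 fallen members (adjusted p of 0.0134), and without Spry1_KO replicate 1, with 4 (0.0394). Of 13 mitochondrially encoded genes, mt-Nd3 alone fell (-1.93), a call lost without Control replicate 1 (limma adjusted p of 0.0649) or 2 (0.0604) or Spry1_KO replicate 1 (0.0693) or 2 (0.0627), and none passed adjusted over the list alone (0.585). Of 3 sex-linked genes none passed (0.977, median 1.44 against a test direction of down). Xist read 60.3 FPKM in controls and 15.5 in knockouts, and Eif2s3y was listed at 0 in the controls. Xist passed as lower without Spry1_KO replicate 2, the library highest in Y-linked genes (limma adjusted p of 0.0216), without Spry1_KO replicate 1 (0.0395), without Control replicate 3 and Spry1_KO replicate 2 together (0.00561), with the replicate block (0.0303), under TPM scaling (0.0352) and scaled to recovered reads (0.0463).

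In all, 13 of the fixed lists passed camera with a preset correlation, and 0 passed with a correlation estimated per list. Some lists that did not pass camera passed fry. These were the Sprouty and Spred (fry adjusted p of 0.00115), hair follicle stem cell (0.0114), hair shaft (0.0139), cytokine (0.035) and suprabasal (0.0403) lists. The FGF list passed fry too (0.0466), with a direction of down where camera gave up.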

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

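The limma-voom fit, the TPM and recovered-read scalings, the fit without both libraries and camera without a variance trend were chosen after seeing the data. No named gene past the threshold changed direction under any setting run. Thy1, Cd2 and Lck, which did not pass, crossed 0. Under TPM scaling they read -0.18, -0.12 and -0.21. Thy1 and Lck read -0.04 and -0.09 scaled to recovered reads and -0.06 and -0.10 with array weights, and Lck read -0.03 under median-ratio scaling. Over the left-out samples Thy1 ran from -0.15 to 0.41, Cd2 from -0.03 to 0.25 and Lck from -0.19 to 0.21. Their SEs were 0.30, 0.18 and 0.23 in the deposited scaling. The cause was not tested. The number of genes past the threshold stayed within 1.5 times of 6815 in every setting but one: asking for a fold of at least 2 as well left 2034. Leaving out single samples gave 5609 to 7290 genes. limma-voom on recovered reads gave 6540. Of the 6815 calls, 5136 were shared, in the same direction, with TPM scaling and 5953 with the fit without Control replicate 3 and Spry1_KO replicate 2. Spry1 ran from -3.62 to -3.82 over the left-out samples. The number of lists past the threshold was 13, and 0 with an estimated correlation; it was 11 to 14 over the left-out samples, 12 without a variance trend in camera and 18 with fry.

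The replicate block gave 5834 genes. Samples with the same number did not deviate together (correlations of -0.098, -0.111 and -0.125). This gives no sign of a pairing by number, though 3 samples per group cannot exclude one. Under the block 161 named genes kept their side of the threshold, 11 no longer passed (Fosb, Awat1, Msx2, Rnf43, Spred2, Jun, Fabp4, mt-Nd3, Hba-a1, Arntl and Cd8a) and Xist came to pass. With no filter 14 no longer passed: these without Rnf43, and Mgst1, Mbp, Btc and Trac. Without Spry1_KO replicate 1, 13 named genes no longer passed, and as many without Spry1_KO replicate 3. In simulated data a 1.5-fold change was recovered in 32.8% of genes. Few genes were changed there and the dispersion was set at 0.02, while 54% of tested genes passed in these data. The share missed here cannot be read from that simulation.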

Other observations

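All tests of explanations here were chosen after the results were seen, and the genes in this paragraph were chosen after their values were seen. Some T cell genes did not fall with those of the gamma-delta receptor, though no list of alpha-beta T cell genes was tested. Trac, of the alpha receptor chain, went from 3.05 ± 1.71 to 8.26 ± 2.77 FPKM (SD, n = 3 each; limma adjusted p of 0.0235), and Cd4 and Cd8a had log2 fold changes of 1.07 and 1.06, the latter not past the threshold without Control replicate 1 (limma adjusted p of 0.0799) or 3 (0.0689). Thy1, Cd2 and Lck, which most T cells share, had log2 fold changes of 0.08, 0.12 and 0.01 and did not pass. The gamma constant segment Tcrg-C1 fell from 38.0 to 5.51 FPKM and Skint9 was 9.84-fold lower in mean FPKM. The cytokine Il19 was listed at 0 in the controls and averaged 45.7 ± 34.6 FPKM in the knockouts, and Il24 had a log2 fold change of 2.58. Of 18 Hox genes tested (no fixed list), 4 rose, 6 fell and 8 did not pass, where 54% of all tested genes passed. Among them, Hoxa5 and Hoxa7 fell by 1.46 and 1.02, and Hoxb9 rose by 0.83, a call lost under TPM scaling (limma adjusted p of 0.0511) and without Control replicate 2 (0.0544).

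Spry1_KO replicate 2 read 15.9 FPKM for Ddx3y and 1.31 FPKM for Xist. The other knockout samples read 0.115 and 0.058 FPKM for Ddx3y and 25.3 and 20.0 FPKM for Xist. The controls read 0 FPKM for Ddx3y and 41.1 to 89.1 FPKM for Xist. The labels give no sex, but by these genes only Spry1_KO replicate 2 read as male. Sex was therefore not balanced between the groups.

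The first pattern is the rise of pigment genes. The scaling of the authors is argued against, since the lowest median of the list under 3 other scalings was 1.69. Hair follicles in full growth, which carry melanocytes, would bring cortex keratins, and these do not settle it. Of 8 such keratins held in the table, Krt83 read 0.207 FPKM in controls and 1.11 in knockouts, while the knockout means of the others were at most 0.0182 FPKM. Krt33a (0.452 FPKM in controls and 0 in knockouts), Krt31 (0.287 and 0.0128), Krt35 (0.218 and 0) and Krt34 (0.0227 and 0) were lower on average. Krt86 (0.0186 and 0.0182), Krt81 (0 and 0.00783) and Krt33b (0 and 0) hardly differed. All 8 had overall means below the filter, and Krt85 was not matched to the table. Early follicle growth stays open too, because 6 inner root sheath keratins, all with overall means below the filter, went both ways. In every knockout sample 2 of them were higher than in every control: Krt73 (0.0416 FPKM in controls and 1.25 in knockouts) and Krt71 (0.146 and 0.536, the nearest samples 0.211 and 0.222). Krt25 (0.0459 and 0.425), Krt27 (0.290 and 0.661) and Krt72 (0.0263 and 0.0385) were higher on average, and Krt28 (0.439 and 0.150) was lower in every knockout sample. Whether more melanocytes or more expression per cell may underlie the rise was not tested.

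The second pattern is the fall of clock genes. Tissue taken at another time of day could give it, since Arntl and Clock, which peak opposite to Dbp, had a median log2 fold change of 0.45, but Clock did not pass (limma adjusted p of 0.0534, and 0.0376 to 0.0468 in the 4 settings where it did). A like fall of all clock genes is argued against only by members of the list itself, whose values were seen before this test was set. At least 4 members lay over 4 SE above the value expected from the list's median FPKM ratio, under each of 4 scalings. In the deposited scaling these were Cry1, Arntl, Clock and Per1, which fell less (-1.13). Scaling moves members and list median nearly alike, so the scalings add no separate support. The time of harvest is not given in the labels, so harvest time and genotype cannot be told apart.

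The third pattern is the fall of Langerhans and T cell genes. Dilution by more keratinocyte RNA, acting alone, would lower all immune genes, but the macrophage and neutrophil list had a median of 2.09. Those are other cells, whose number may have changed separately. Whether Langerhans and T cell RNA was diluted therefore stays open. Scaling is argued against by medians of -1.41 or lower under 3 other scalings. A like loss of all T cells is argued against only by members of the list itself, whose values were seen before this test was set. In the deposited scaling Thy1, Cd2 and Lck lay over 4 SE above the value such a loss would give. At least 3 members did so under each of 4 scalings. Scaling moves members and list median nearly alike, so the scalings add no separate support. Trac rose by 1.24, a call lost without Control replicate 1 (limma adjusted p of 0.0546) and without Spry1_KO replicate 1 (0.0782) or 3 (0.0705). Its log2 fold change was still 1.27, 1.03 and 1.21 in these fits. Fewer cells of one T cell type, or lower expression per cell, stays open.

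The 6 samples allow 10 splits into equal groups, too few for a share under 0.05. The real split gave 6815 genes and the highest of the others 0 (limma; 50 to 327 genes at an unadjusted p under 0.05). For lists in camera the real split gave 13 and the highest of the others 17, and 5 of the 10 splits gave as many. Each other split mixes the genotypes, so part of their difference stays between the groups and the rest widens the spread within them. That spread makes calls of single genes unlikely there from the outset. The splits therefore do not show how many genes or lists chance would call.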
